A study of Mus musculus and Bos taurus with 6 samples.

How the data were processed

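Chromatin from fetal testis was immunoprecipitated with an antibody against SOX9 and sequenced in mouse and cattle. The labels list 6 libraries. Each species has 2 SOX9 libraries and 1 input library, which is sheared chromatin DNA sequenced without immunoprecipitation. Mouse gonads (Swiss OF1 strain) were taken at stage E13.5 and Holstein bovine gonads at day 90. Per the labels' protocols, the powdered tissue was cross-linked first with disuccinimidyl glutarate, a protein cross-linker, and then with formaldehyde. Double cross-linking also retains proteins that reach DNA through another protein, so a peak need not lie on a sequence that SOX9 itself contacts. The antibody was raised in rabbit and the same reference is given for both species.

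The authors deposited 1 peak list per species, and the labels assign the same list to both SOX9 libraries and the input of that species. Each line holds a chromosome, a start, an end and 1 further value. This value was checked and equals end minus start in every line, so it is the peak width in base pairs. The deposited lists hold no peak height, fold enrichment, p-value or read count. The aligner, the peak caller, its threshold and the way in which replicates and input were combined are not given in the sources used here. Sequencing depth is therefore unknown, and no value per library could be formed. The submitters' processing notes name the builds mm9 and UMD3.1, which were taken as the builds of the mouse and the bovine list. The builds themselves were not tested against chromosome lengths. All positions below are printed counted from 1, in mm9 for mouse and UMD3.1 for cattle.

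No genome sequence or gene annotation of mm9 or UMD3.1 was used here, and positions were not converted between builds. Tests planned before the data were examined that need a matching annotation or sequence were therefore not run. These are the position of peaks relative to genes, the binding of fixed gene lists, the genes bound in both species and the motif content of peaks. No gene is named as bound for that reason. The planned description of peak scores was also not run, because the lists hold no score, and wherever a plan called for ranking by score the width was used, as the plan allowed. The mouse peaks used here lie on chromosomes 1 to 15, 17 to 19 and the X, and the bovine peaks on chromosomes 1 to 29 and the X. Mouse chromosome 16 and the Y of both species were not analysed here, and whether further peaks of a listed chromosome were set aside before this work, the mouse X included, is not known.

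Peak density was the number of peaks divided by the span of the chromosome, from the first to the last peak in the list, since chromosome lengths of these builds were not used here. The density of each chromosome is given with its exact 95% Poisson interval. The share of peaks on each chromosome was set against its share of the summed span by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the chromosomes of a species. X and autosomes were compared by the ratio of their densities with an exact conditional interval. Widths on the X and on autosomes were compared by a two-sided permutation test of the difference of medians with 100000 permutations. Peaks with a neighbour within 10 kb, edge to edge, were counted and compared with 10000 random placements of the same peaks within the same chromosome spans, one-sided. Where close peaks were first merged, the randomly placed peaks were merged by the same rule. All peaks of the list were placed for this. The number of regions left after merging was not matched to the real 6208 in mouse and 11281 in cattle. The placements took no account of assembly gaps or of sequence to which reads cannot be mapped, where no peak can be called. Windows of 1 Mb had their boundaries set from the start of each chromosome, a peak was assigned by its midpoint, and only windows that touch the span from the first to the last peak were counted. The peaks and windows to be named were fixed before the data were examined as the 10 widest peaks and the 5 densest 1 Mb windows per species. Other regions named below were chosen after their values were seen. The direct ratio of X to autosomes and its difference between species, the widths on the X, the frequency of gaps and the relation of width to the nearest peak were added after the lists had been seen.

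These intervals and tests cover counting error only. Peaks of 1 list are not biological replicates and neighbouring peaks are not independent, so the p-values describe how a list departs from an even spread and say nothing of animals. Differences between the species' lists have no replicate error.

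The tests were tried on simulated data. Of 20 evenly spread lists per species, 2 mouse lists and 0 bovine lists were called clustered at the 0.05 level, and after merging 3 and 1 were. These trials used fewer placements than the real lists, and placement over the whole span only. All 20 lists per species were called when 5% of peaks had been given a planted neighbour. At least 1 chromosome was called in 1 of the 20 evenly spread mouse lists of 6419 peaks and in 0 of the 20 bovine lists of 11988 peaks. A planted X to autosome ratio of 0.2 came back as 0.205 on average for mouse and 0.195 for cattle, and 19 of 20 intervals held it in each. The ratio trials used the spans of the real lists, not spans taken from the simulated peaks. A ratio as low as the 0.0460 of the mouse list was not tried. Alternatives were the widest 50% of peaks, merging of close peaks, other neighbour distances, local placement and another denominator for density. Leaving out replicates was planned and could not be run. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.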

Results

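SOX9 is the HMG-box transcription factor that directs the supporting cells of the fetal gonad to become Sertoli cells. Its occupancy was profiled by ChIP-seq in fetal testes of mouse at stage E13.5 and of cattle at day 90, with 2 immunoprecipitated libraries and 1 input library per species. The labels state the purpose as examining the role of SOX9 in the fetal testis. Each species is represented by 1 list of bound regions that stands for its libraries together. The spread between replicates could therefore not be measured for any value below. The number of reads behind the lists is unknown.

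The mouse list held 6419 SOX9 peaks on 18 autosomes and the X, and the bovine list held 11988 peaks on 29 autosomes and the X. The bovine list was thus 1.87 times as long. Mouse peaks had a median width of 953 bp (95% interval of the median 942 to 964 bp), with quartiles at 742 and 1212 bp. Bovine peaks were wider, with a median of 1222 bp (95% interval 1215 to 1232 bp) and quartiles at 958 and 1504 bp. Together the peaks covered 6.54 Mb in mouse and 15.1 Mb in cattle. Peaks over 2000 bp made up 2.21% of the mouse list (142 peaks) and 4.32% of the bovine list (518 peaks). With 1 list per species, a difference in depth, threshold or peak calling could not be separated from a difference between species or stages.

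**Figure D1:**
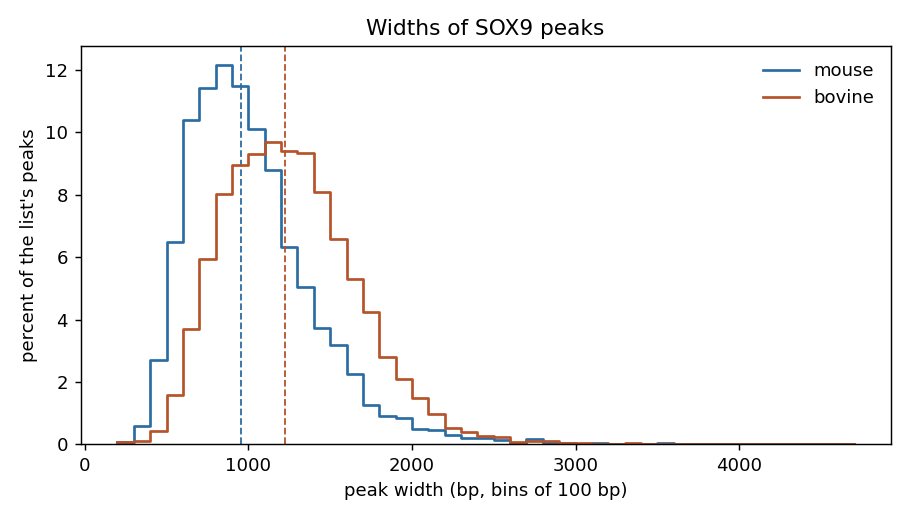
Distribution of peak widths in the mouse and bovine lists, as the percent of each list's peaks (vertical axis) per 100 bp bin of width in bp (horizontal axis); dashed lines mark the medians of 953 bp in mouse and 1222 bp in cattle. The bovine distribution lies to the right of the mouse distribution.

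The widest mouse region lay on chromosome 19 from 53384716 to 53388719 (mm9) and measured 4004 bp. It was followed by a region of 3938 bp on chromosome 14 (47501551 to 47505488), one of 3587 bp on chromosome 6 (99470328 to 99473914), one of 3535 bp on chromosome 11 (51669180 to 51672714) and one of 3511 bp on chromosome 10 (13684302 to 13687812). The next in width were 3379 bp on chromosome 18 (39648424 to 39651802), 3198 bp on chromosome 5 (52504463 to 52507660), 3172 bp on chromosome 2 (127950933 to 127954104), 3035 bp on chromosome 13 (55311058 to 55314092) and 2984 bp on chromosome 4 (87677204 to 87680187). The widest bovine region lay on chromosome 1 from 98392120 to 98396883 (UMD3.1) and measured 4764 bp. Regions of 3875 bp on chromosome 3 (8102309 to 8106183), 3864 bp on chromosome 13 (3873873 to 3877736), 3570 bp on chromosome 11 (64766995 to 64770564) and 3528 bp on chromosome 21 (37272324 to 37275851) came next. The remaining bovine regions among the 10 widest measured 3410 bp on chromosome 4 (46472690 to 46476099), 3341 bp on chromosome 6 (45588096 to 45591436), 3317 bp on chromosome 21 (45383756 to 45387072), 3315 bp on chromosome 13 (76625047 to 76628361) and 3208 bp on chromosome 18 (34392086 to 34395293). None of the 10 widest regions of either species lay on the X. Which genes flank these regions was not analysed here.

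SOX9 peaks were spread unevenly over the chromosomes of both species. Mouse chromosome 11 was the densest, with 552 peaks or 4.66 per Mb (95% Poisson interval 4.28 to 5.07), which was 1.77 times its share by span (exact binomial test, adjusted p = 2.0e-35). Chromosome 19 followed with 4.10 peaks per Mb (3.60 to 4.66) and chromosome 9 with 3.32 (3.01 to 3.67). The sparsest mouse autosome was chromosome 1, with 398 peaks or 2.06 per Mb (1.86 to 2.27). Of the 19 mouse chromosomes, 7 held more peaks and 6 held fewer than their share after adjustment. When the X was left out of the total, 3 autosomes held more (9, 11 and 19) and 7 held fewer than their share.

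In cattle, chromosome 19 was the densest, with 731 peaks or 12.4 per Mb (11.5 to 13.3), 2.71 times its share by span (exact binomial test, adjusted p = 3.4e-121). Chromosome 25 held 10.2 peaks per Mb (9.31 to 11.3), chromosome 18 held 9.57 (8.84 to 10.4) and chromosome 23 held 7.02 (6.32 to 7.78). The sparsest bovine autosomes were chromosome 20 with 2.54 peaks per Mb (2.18 to 2.93), chromosome 6 with 2.61 (2.33 to 2.92) and chromosome 12 with 2.66 (2.33 to 3.01). Of the 30 bovine chromosomes, 11 held more and 12 held fewer peaks than their share. Among the widest 50% of peaks of each list, 8 mouse and 20 bovine chromosomes departed from their share, against 13 and 23 in the full lists.

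**Figure D2:**
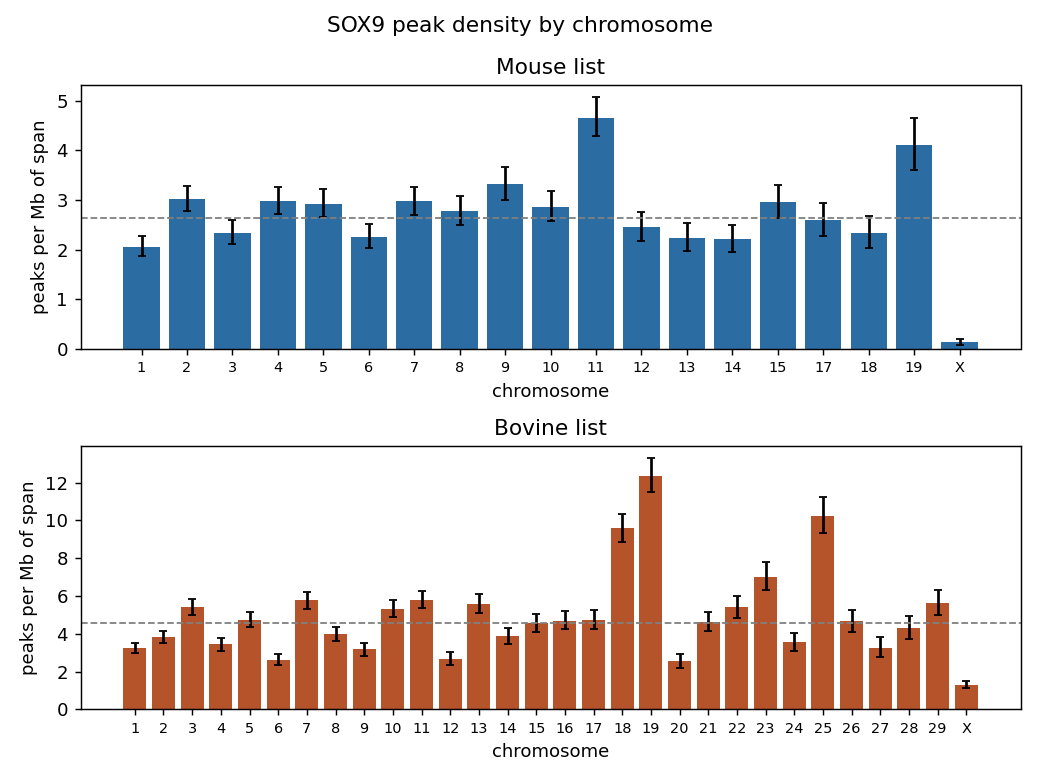
SOX9 peaks per Mb of chromosome span (vertical axis) for each chromosome (horizontal axis) of the mouse list (top) and the bovine list (bottom); bars give the density, error bars its exact 95% Poisson interval and dashed lines the density of the whole list, 2.64 and 4.56 peaks per Mb. Mouse chromosome 11 and bovine chromosome 19 stand highest and the X lowest in both lists.

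The X chromosome carried far fewer SOX9 peaks than the autosomes in both species, and the deficit was larger in the mouse list. Testis cells carry a single X. The mouse X held 17 peaks over 133 Mb, or 0.128 per Mb (0.0747 to 0.205), against 2.79 per Mb over all autosomes. The ratio of X to autosome density was 0.0460 (95% exact interval 0.0268 to 0.0738, p = 1.3e-127), and among the widest 50% of mouse peaks, of which 4 lay on the X, it was 0.0216. The bovine X held 192 peaks over 147 Mb, or 1.31 per Mb (1.13 to 1.51), against 4.75 per Mb on autosomes. Its ratio was 0.276 (0.238 to 0.318, exact p = 7.6e-109). The mouse ratio was 0.167 times the bovine ratio, and 0.0946 times among the widest 50% of peaks of each list. Of the 209 X peaks of both lists, 8.13% were in the mouse list where equal ratios would give 34.7% (exact binomial test, two-sided p = 3.3e-19).

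Peaks on the X were also narrower. The median width of the 17 mouse X peaks was 629 bp (quartiles 544 and 918 bp) and that of the 6402 autosomal peaks 953.5 bp, a difference of -324.5 bp (permutation test, two-sided p = 0.0037, adjusted over both species 0.0074). In cattle the medians were 1132.5 bp on the X and 1224 bp on autosomes, a difference of -91.5 bp (permutation test, two-sided p = 0.017, adjusted p = 0.017).

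Within chromosomes, SOX9 peaks gathered in neighbourhoods. The densest 1 Mb windows of the mouse genome were on chromosome 11 from 69000001 to 70000000 with 20 peaks, chromosome 10 from 79000001 to 80000000 with 19, chromosome 10 from 127000001 to 128000000 and chromosome 11 from 102000001 to 103000000 with 18 each. The fifth place was shared by 5 windows of 17 peaks on chromosomes 2 (32000001 to 33000000), 7 (134000001 to 135000000), 8 (86000001 to 87000000 and 108000001 to 109000000) and 9 (44000001 to 45000000). The densest bovine windows were on chromosome 25 from 36000001 to 37000000 with 44 peaks and chromosome 19 from 27000001 to 28000000 with 41. They were followed by chromosome 25 from 26000001 to 27000000 with 36 and from 1000001 to 2000000 with 35, and by chromosome 19 from 43000001 to 44000000 and chromosome 29 from 44000001 to 45000000 with 34 each. The most densely filled 10% of windows held 36.6% of mouse peaks and 37.8% of bovine peaks, against at most 24.5% in any of 1000 even placements within chromosomes of either list. The fullest single window in those placements held 18 peaks in mouse and 30 in cattle. Among the named mouse windows only those of 20 and 19 peaks exceeded this, while all named bovine windows did. Within the spans from first to last peak, windows without a peak made up 30.3% of 2449 mouse windows and 20.1% of 2657 bovine windows, against at most 13.3% and 4.74% in those placements. Assembly gaps and unmappable sequence were open to these placements and to those used for neighbours below. Part of each excess over placement may therefore come from such stretches, which was not tested. The longest autosomal stretches without a peak, chosen after the values were seen, were 12.2 Mb on mouse chromosome 15 (13103639 to 25341752) and 13.6 Mb on bovine chromosome 20 (42416302 to 56020660).

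**Figure D3:**
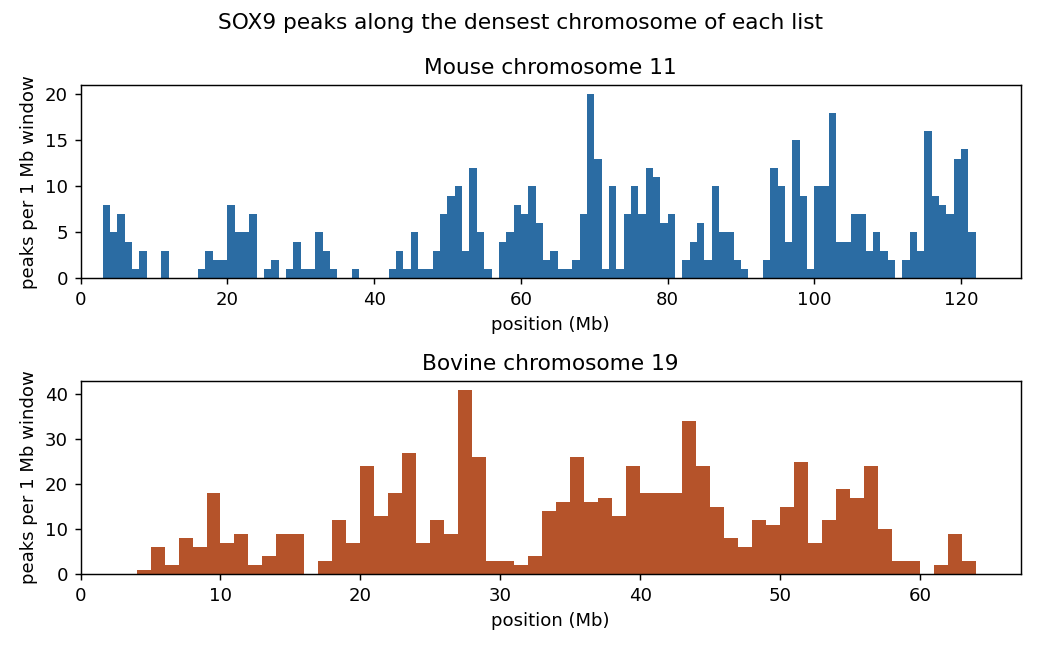
Number of SOX9 peaks per 1 Mb window (vertical axis) along mouse chromosome 11 in mm9 (top) and bovine chromosome 19 in UMD3.1 (bottom), with position in Mb on the horizontal axis. The tallest bars are the windows of 20 peaks in mouse and 41 peaks in cattle.

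At short range, 14.9% of mouse peaks and 30.3% of bovine peaks had another peak within 10 kb. Even placement gave 6.19% ± 0.417 (SD over 10000 placements) in mouse and 11.4% ± 0.386 in cattle, so that the observed shares were 2.41 and 2.64 times as high (one-sided permutation test by random placement, p = 0.0001 in both, the smallest the placements can give). Clusters of at least 2 peaks numbered 456 in mouse and 1632 in cattle, and 41 and 284 of them held at least 3. The largest mouse cluster held 5 peaks in 22.1 kb of chromosome 2 (17947656 to 17969732). In cattle 4 clusters held 6 peaks each, on chromosome 7 (4668273 to 4693274), chromosome 25 (36469280 to 36508504 and 39422495 to 39433165) and chromosome 28 (31313459 to 31328964). These clusters were chosen after their values were seen.

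Part of the neighbours lay almost edge to edge. Gaps under 500 bp numbered 211 of 6400 in mouse (3.30%) and 707 of 11958 in cattle (5.91%). After such pairs were merged, 8.99% of mouse and 20.9% of bovine regions still had a neighbour within 10 kb. Even placement over the whole span, merged by the same rule, gave 5.36% ± 0.393 in mouse and 9.75% ± 0.365 in cattle. The observed shares were 1.68 and 2.14 times as high. Without merging, placement within 1 Mb of each peak gave 10.2% ± 0.494 and 17.9% ± 0.443. The unmerged shares were 1.46 and 1.69 times as high. Both settings were planned. Their combination, given next, was chosen after the data were seen. With placements restricted to 1 Mb around each peak and merged in the same way, the expected shares were 8.22% ± 0.465 in mouse (1.09 times, one-sided permutation test by placement, p = 0.049) and 14.6% ± 0.425 in cattle (1.44 times, p = 0.0001). The frequency of gaps from 500 bp to 1 kb, which were not merged, was still raised. It was 76.0 gaps per kb of gap length (53.8 to 104) in the mouse list and 308 (261 to 361) in the bovine list. Beyond 1 kb the frequency of gaps in the mouse list was flat, at 31.0 gaps per kb of gap length (21.1 to 44.0) between 1 and 2 kb and 27.9 (26.0 to 29.8) between 20 and 50 kb. In the bovine list it fell over the same distances from 174 (149 to 202) to 72.5 (69.5 to 75.6).

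**Figure D4:**
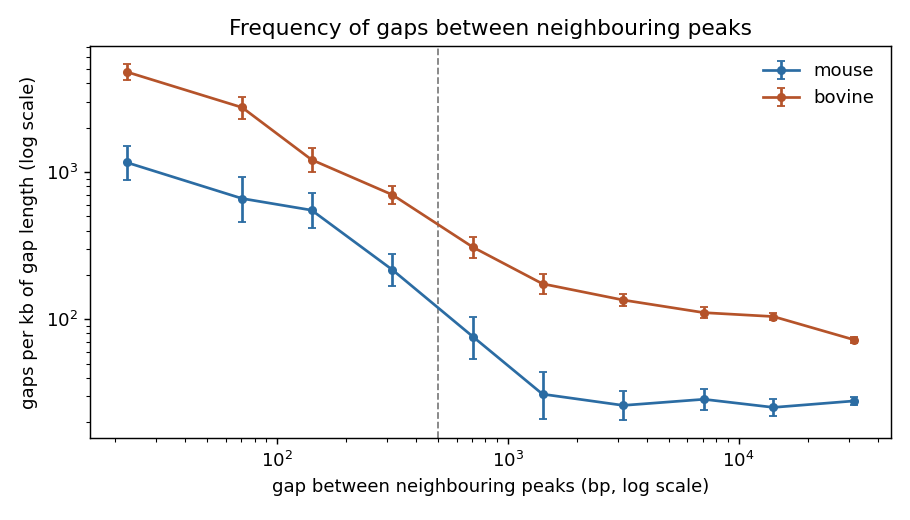
Number of gaps between neighbouring peaks per kb of gap length (vertical axis, log scale) against gap length in bp (horizontal axis, log scale), with exact 95% Poisson intervals; the dashed line marks 500 bp. Both lists rise steeply toward gaps under 50 bp, and beyond 1 kb the mouse list is flat while the bovine list keeps falling.

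Peaks that stood alone were wider than peaks with close company. Across the 6419 mouse peaks, width rose with the distance to the nearest peak (Spearman's rho = 0.15, permutation test, two-sided p = 1e-05, the smallest the permutations can give), and across the 11988 bovine peaks rho was 0.19 (p = 1e-05, again the smallest). Without the peaks in pairs less than 500 bp apart, rho was 0.11 in both species (p = 1e-05 in each). The 415 mouse peaks in such pairs had a median width of 781 bp against 965 bp for the others, and the 1380 bovine peaks 1003 bp against 1254 bp (permutation test, two-sided p = 0.0001 in both, the smallest that 10000 permutations can give). These correlations are across peaks of 1 list, which are not independent replicates.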

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

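Of the tests in this part, the ones on the single X copy and on a missing block as run here, the test of the difference between species and its alternatives were chosen only after the result was seen. The density of SOX9 peaks on the X relative to autosomes differed between the species, the mouse ratio being 0.167 times the bovine ratio by a test of the difference itself. The ratio stayed between 0.0946 (widest 50% of each list) and 0.161 (clusters within 10 kb counted once) under both alternatives tried. The value of 0.0946 rests on 4 mouse X peaks. X peaks fell further short of autosomal widths in mouse than in cattle, so keeping the widest peaks is not an independent check. A smaller number of genes on the mouse X was tested as an explanation of the mouse deficit. A line through the 18 autosomes put the X at 2.52 peaks per Mb with a 95% prediction interval from 1.55 to 3.50. The observed 0.128 lies below that interval, which argues against gene number as the whole cause. All 966 genes of the X were divided by the 133 Mb span of its peaks, without the 33.9 Mb before the first peak. This overstates the X's gene density and raises its fitted value. A single missing block of the X was tested within the span from its first to its last peak, which already leaves out the 33.9 Mb without a peak before the first one. Outside the longest peak-free stretch there, 16.6 Mb, the upper bound of the density was 0.235 peaks per Mb, under the 2.06 of the sparsest autosome, which argues against 1 missing block as the whole cause, at the start or within the span.

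The single X copy of male cells, which lowers both the immunoprecipitated and the input signal, may contribute in both species: the X ratio was low in the bovine list too (0.276) and X peaks were narrower than autosomal ones in both lists. How many peaks a lower signal would remove depends on their heights and on the calling threshold, which were not used here, so this explanation cannot be told apart from lower occupancy of the X in testis cells. Species and stage change together between the lists, and depth and calling are unknown and may differ as well. No biological explanation of the difference between species was tested. Mouse chromosome 16 was not analysed here, and peaks of the X set aside in several places before this work would also leave this pattern; this was not tested.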

How the results depend on the processing

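Of 44 alternative values, 7 moved. The other 37 kept their direction and side of the threshold, or stayed within 1.5 times (counts) or the 95% interval (median widths). Of these, the count of mouse chromosomes off their share went from 13 to 10 without the X, and its split from 7 denser and 6 sparser to 3 and 7. Keeping only the widest 50% of peaks lowered the number of peaks to 3213 in mouse and 6002 in cattle and raised the median width to 1211 and 1504 bp, as its construction requires. Merging peaks less than 500 bp apart gave median widths of 982 and 1284 bp, since 2 peaks become 1. Among the widest 50%, 8 mouse chromosomes departed from their share of peaks against 13, with fewer peaks tested. Restricting the lists to numbered autosomes and X removed nothing, so its values, counted among the 37, could not move. The excess of peaks with a neighbour ranged from 1.09 to 3.14 times the random share in mouse and from 1.44 to 3.45 in cattle. Its lowest value in both came from merging together with local placement, an alternative chosen after seeing the data, as were leaving out the X, the X width test with its merging, and the X to autosome ratios with their alternatives. Those ratios ranged from 0.0216 to 0.0499 in mouse and from 0.228 to 0.311 in cattle. Under merging together with local placement, the mouse excess of neighbours had a one-sided permutation p of 0.049, near the threshold. With merging and placement over the whole span, 3 of 20 evenly spread simulated mouse lists passed the test. The test with local placement was not tried on simulated lists. No paired analysis was possible because each species has 1 list for all of its libraries, so replicate numbers carry no values. Leaving out each replicate was not possible for the same reason. The alternatives planned for scores, genes, shared genes and motifs were not run, for want of scores and of a matching annotation or genome sequence here. Read depth is unknown, so neither list shows which regions were too shallow to be called.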

Other observations

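Of the tests in this part, those of the gaps between peaks and of merged peaks under local placement were chosen only after the result was seen. Across mouse autosomes, SOX9 peaks followed the number of genes. The density of peaks rose with the number of protein-coding genes per Mb over the 18 autosomes (Pearson's r = 0.77, permutation p = 0.0003; Spearman's rho = 0.80, permutation p = 0.00013; adjusted over these 2 tests 0.0003 and 0.00026). Gene numbers per chromosome came from a gene table of mouse build GRCm38 and were used only as counts. Without chromosomes 7 and 11, the 2 farthest from the median gene density, r was 0.76 (permutation p = 0.00048) and rho 0.77 (permutation p = 0.00072). Both densities share the span as denominator, and after removal of log span from the logs of both counts r was 0.77 (permutation p = 0.0001). Chromosome 7 held 0.218 and chromosome 17 held 0.223 peaks per gene, the lowest autosomal values, chromosome 12 the highest at 0.423, and the X 0.0176. Gene content is therefore a candidate explanation for much of the difference between mouse autosomes, and the same test was not run in cattle. The Sox9 gene is itself on mouse chromosome 11, the densest chromosome. No link between the 2 was tested, and chromosome 11 held 0.343 peaks per gene, inside the range of the autosomes.

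The excess of neighbours almost edge to edge may come from 1 broad enriched region divided into adjoining peaks. Gaps under 500 bp were 12.9 times as frequent per bp as gaps from 500 bp to 5 kb in mouse (95% exact interval 10.4 to 16.1) and 8.68 times in cattle (7.82 to 9.64) and 58 mouse and 239 bovine gaps were under 50 bp. Peaks in such pairs were also narrower. Width still rose with distance to the nearest peak when these pairs were left out (Spearman's rho 0.11 in both species). Narrower width near a neighbour is thus not particular to such pairs and cannot decide for this explanation. Distinct binding sites that close together would give the same gaps, and no read profile was used here to separate them. With gaps under 500 bp merged away, the share of regions with a neighbour within 10 kb was 1.44 times that under local placement in the bovine list and 1.09 times in the mouse list. The difference between them was not tested. Gaps from 500 bp to 1 kb, which this merging leaves, were more frequent than gaps from 1 to 2 kb in both lists. What remains after merging may thus still include part of the excess of close gaps, which was not tested.

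A preference for the distal side of chromosomes was tested as a hypothesis, since autosomes of both species have their centromere at one end. Peaks were more numerous beyond the midpoint of the span, away from its start, on 12 of 17 untied mouse autosomes (exact two-sided sign test, p = 0.14) and on 20 of 29 bovine autosomes (p = 0.061, adjusted over both 0.12), and 56.9% and 55.5% of autosomal peaks lay there. Neither test passed the threshold. A p above it was a poor bound to exclude a preference of this size with so few chromosomes, so the question stays open. With the X included, the counts were 13 of 18 untied mouse chromosomes (exact sign test, p = 0.096) and 21 of 30 bovine chromosomes (p = 0.043), both unadjusted. The premise of a centromere at one end was given for autosomes only. Where the centromere of the X lies was not examined, so the counts with the X do not bear on a distal side.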
